A study of Gallus gallus with 16 samples.

How the data were processed

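The study profiled histone marks in lens fiber cells of embryonic day 13 chick (Gallus gallus) lenses by CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA around a chromatin mark. Per the labels, lenses were kept for 2 h at 21% oxygen (normoxia) or 1% oxygen (hypoxia), and each replicate held 10 to 15 lenses. The extraction text instead describes dissection at 0 h or 2 h of hypoxia, so it stays open whether the normoxia lenses were also cultured for 2 h. The labels list 16 libraries. H3K27ac, an acetyl mark of active promoters and enhancers, has 2 libraries per condition. H3K4me3, a methyl mark of active promoters, has 3 per condition, and the nonspecific antibody control IgG has 3 per condition. Groups were taken from the labels of each library.

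The deposited table holds 1 list of peaks for each of the 2 marks in each condition, 4 lists in all, and per the file headers it gives each peak's chromosome, start, end, width, nearest gene, transcript, distance to the transcription start site (TSS) and genomic class. It carries no value per library, no peak score or enrichment and no p-value, and IgG was not analysed here. The submitters' processing notes name STAR, DESeq2, MACS2 and ChIPseeker and the chicken build galGal6, with no version and no role for any of them. Whether the authors called peaks on pooled reads or merged calls of single libraries is not given in the sources used here, nor are the threshold and the control used. The read depth of each library is therefore unknown. The binomial intervals below (Wilson, 95%) cover the counting of peaks or genes only, not the spread between lenses, and the lists allow no test against replicates. Peaks and genes are not replicates, so no p-value was computed across them.

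The table has 124414 lines. Of these, 15894 repeat the interval of an earlier line of the same list, mostly because 8378 peaks are annotated to more than 1 transcript, and 1384 are identical in every field. Each interval was counted once, which left 108520 peaks on 34 chromosomes, from 162 to 43035 bp wide. Starts follow the BED convention and are printed 1-based. No pair of neighbouring peaks in a list lay closer than 656 bp. Gene names are those of the table: it names 14100 gene IDs, of which 1221 have no symbol of their own. Members of a gene list were counted by gene ID. Unless all listed names are given, members are only the genes with a promoter peak (defined below) of either mark. No genome sequence was used.

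Peaks of the normoxia and hypoxia lists of a mark were called shared where they overlapped by at least 1 bp (overlap counts were checked against bedtools 2.31.1). The overlap expected by chance came from 100 circular shifts of the other list along each chromosome. A promoter peak was one that the table places within 3000 bp of the TSS. A gene's promoter was in both lists if it had a promoter peak in each, or if its promoter peak overlapped any peak of the other list. It was in the hypoxia list only or the normoxia list only otherwise. Gene lists were compared with 10000 random lists of the same size, drawn from genes with any promoter peak and matched on the width of the promoter peak of the other mark in 5 classes. A list stands apart where its percentile lies below 2.5 or above 97.5, which describes these lists of peaks and is no test between conditions. The method was tested on simulated states of 11000 genes that depended on the width used for matching, with 200 lists of 20 wide genes each. Of lists drawn at random among wide genes, 2% passed the upper bound. So did 77% of lists in which genes of the state were 4 times as likely to be drawn. This checks the matching in that setting only, not the percentiles reported below. Covered length is the summed width of the peaks annotated to a gene, and width stands in for strength throughout because the table holds no signal. A peak annotated to several genes counts for each of them. Random lists were not matched on normoxia coverage, from which covered ratios are formed.

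The 18 gene lists, the 10 genes reported in any case (BNIP3L, EGLN3, PDK1, VEGFA, LDHA, CDKN1B, CRYAA, MIP, BFSP1 and PAX6), the overlap rules, the promoter window and the plan to describe overlaps if the table held peaks alone were fixed before the data were examined. The planned count model, its gene set test and the Fisher tests between states were replaced by shares, odds ratios, ratios of observed to expected counts and matched random lists. The other named genes are, for each mark and direction, the 10 with the widest promoter peak present in 1 condition only, and up to 3 such members of each gene list, with some members in both lists or in neither; a few genes that this rule names are not reported here. The plan ranked them by fold enrichment, which the table does not hold, so ranking by width was chosen after the table was seen. Alternatives covered stricter and looser overlap rules, promoter windows of 1000 bp, every peak annotated to a gene, peaks at least 500 bp wide, lists of equal length, autosomes only, transcript starts inferred from the table's distances and, for covered ratios outside the middle 95%, each list member left out in turn. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.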

Results

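The series asks how low oxygen changes activating histone marks across the genome of lens fiber cells, the elongated cells that fill the lens and lie far from any blood supply. Peaks of H3K27ac (2 libraries per condition) and H3K4me3 (3 libraries per condition) were listed for embryonic day 13 chick lenses. Per the labels, the lenses were kept for 2 h at 21% or at 1% oxygen. Whether the normoxia lenses were cultured for 2 h stays open. Each mark has 1 list per condition, with no value per library, so the differences below have no replicate check, and the depth behind each list is unknown. Coordinates refer to galGal6.

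H3K27ac was listed at far more places in hypoxia than in normoxia. The hypoxia list held 45734 peaks over 36.9 Mb and the normoxia list 15511 peaks over 11.0 Mb, 2.95 times as many peaks and 3.34 times the covered length. Median peak widths were close, 564 bp in hypoxia and 535 bp in normoxia. Of the normoxia peaks, 60.7% (95% interval 59.9 to 61.5%) overlapped a hypoxia peak, against 7.48% under circular shifts. Of the hypoxia peaks, 19.3% (19.0 to 19.7%) overlapped a normoxia peak, against 2.51% by shifts, so 36897 peaks were in the hypoxia list only and 6093 in the normoxia list only.

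The peaks in the hypoxia list only lay away from promoters more often than the shared ones. Of them, 13.2% were within 1 kb of a TSS, 32.6% in introns and 26.1% in distal intergenic sequence, compared with 34.4%, 24.1% and 17.0% of the shared hypoxia peaks. The odds of lying within 1 kb of a TSS were 0.29 times those of shared peaks. H3K4me3 peaks of either condition overlapped 31.0% of the hypoxia-only peaks and 73.3% of the shared ones. Peaks listed in hypoxia only were also narrower, with a median of 481 bp against 1243 bp. Normoxia-only H3K27ac peaks differed from shared normoxia peaks in the same directions, so these traits were not particular to hypoxia-only peaks. Of the normoxia-only peaks, 19.7% lay within 1 kb of a TSS, against 31.1% of the shared ones. H3K4me3 peaks overlapped 44.4% against 69.8%, and median widths were 364 and 678 bp. When the normoxia list was split into 10 equal classes by width, the widest class overlapped hypoxia peaks in 94.5% of cases and the narrowest in 31.7%. With the hypoxia list reduced to its 15511 widest peaks, 9332 were in that list only, and where overlap had to reach 50% of both peaks, 13093 normoxia peaks were in the normoxia list only.

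**Figure D1:**
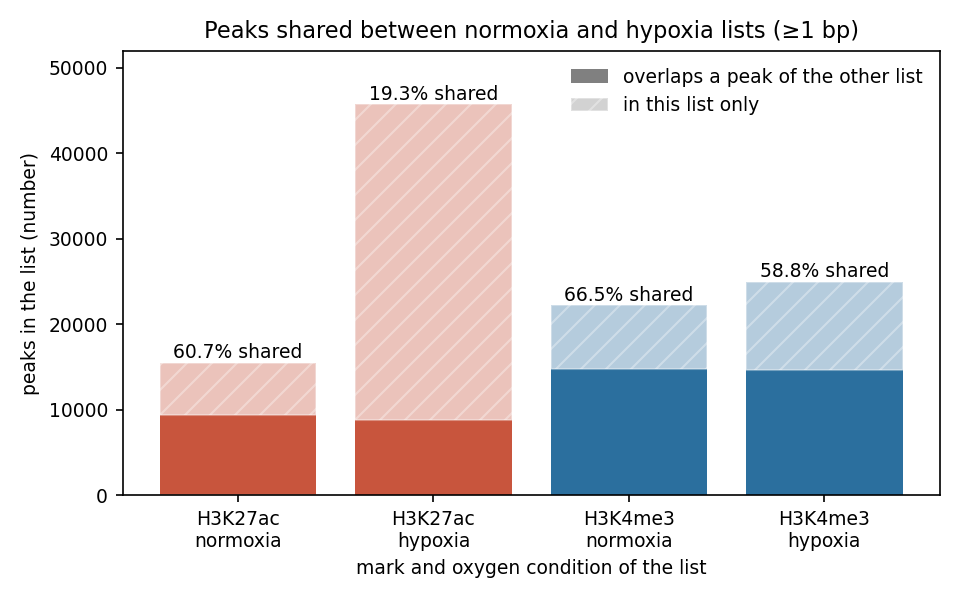
Number of peaks in each of the 4 lists (y axis) by mark and oxygen condition (x axis). Solid parts are peaks overlapping the other condition's list of the same mark by at least 1 bp and hatched parts are the rest: 36897 of the 45734 hypoxia H3K27ac peaks have no normoxia partner, while 58.8% of the hypoxia H3K4me3 peaks have one.

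At promoters, H3K27ac was present in both conditions at 4364 genes, in the hypoxia list only at 4370 and in the normoxia list only at 561. These are 47.0%, 47.0% and 6.04% of the 9295 genes with an H3K27ac promoter peak. In the 4159 genes with promoter peaks of their own in both lists, the promoter peaks covered a median of 743 bp in normoxia and 1634 bp in hypoxia, a median log2 ratio of 1.04, and 78.8% of these genes were wider in hypoxia. The widest promoter peaks of the hypoxia list only belonged to C1D, which encodes a cofactor of the nuclear exosome (4753 bp at chromosome 3, 11841137 to 11845889, 534 bp downstream of the TSS), to the ribosomal protein gene RPL36AL (4547 bp), to BTAF1, an ATPase that removes TATA-binding protein from DNA (4448 bp), to TMEM183A (4351 bp), to the actin-related chromatin remodeling gene ACTR6 (4315 bp) and to LNP1 (4217 bp). A single peak of 4555 bp on chromosome 15 (6586001 to 6590555) covered the promoters of NAA25, a subunit of an N-terminal acetyltransferase, and TRAFD1. A single peak of 4264 bp on chromosome 22 covered those of the magnesium transporter gene CNNM4 and the lectin gene LMAN2L. The widest promoter peaks of the normoxia list only were narrower. They lay at the endothelial receptor kinase gene TIE1 (2246 bp), HMGB1, which encodes an abundant chromatin protein (1891 bp), PBDC1 (1658 bp), the potassium channel gene KCND2 (1602 bp), the RNA-binding protein gene KHDRBS1 (1459 bp), FKBP14 (1457 bp), ADPRHL (1438 bp) and the lipid kinase gene PIP4K2B (1437 bp). A peak of 1435 bp served both CPSF7, of the mRNA 3' end processing machinery, and SDHAF2, an assembly factor of succinate dehydrogenase. Over all annotated peaks, 5 hypoxia peaks lay elsewhere at HMGB1, 3 at PBDC1, 6 at KCND2 and 1 at KHDRBS1, outside their promoter windows. Coverage in normoxia and hypoxia was 2.11 and 3.66 kb at HMGB1, 3.07 and 3.44 kb at PBDC1 and 1.91 and 3.24 kb at KCND2. At KHDRBS1 it was 1.46 and 0.717 kb. The other named normoxia-only genes had no hypoxia peak. Of the named hypoxia-only genes, BTAF1 had 4 normoxia peaks outside its promoter window, and C1D, NAA25 and TRAFD1 had 1 each. The rest had none.

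Genes of the fiber cell itself already carried H3K27ac in normoxia. Of 19 lens fiber structural genes, 17 had a promoter peak in both lists, at percentile 99.98 of matched random lists, and ASL1 (delta crystallin, 1490 bp) and LGSN (lengsin, 693 bp) were in the hypoxia list only. Their H3K27ac covered 80.0 kb in normoxia and 131 kb in hypoxia, a ratio of 1.64, whereas matched random lists had a median ratio of 3.15 (percentile 0.01, and at most 0.14 with any 1 member left out). The random lists were not matched on normoxia H3K27ac, so this low ratio cannot be told apart from high coverage already in normoxia. At CRYAA, the chaperone alpha A crystallin, the peak over the TSS was 3467 bp in normoxia and 3451 bp in hypoxia, and the gene had 7 and 6 peaks covering 12.8 and 15.8 kb. At MIP, the water channel of fiber cell membranes, the only peak was 3163 bp in normoxia and 1675 bp in hypoxia. BFSP1, a filament protein of fiber cells, had 9 peaks over 7.81 kb in normoxia and 5 peaks over 12.2 kb in hypoxia, of which 1 spanned 12095923 to 12102087 on chromosome 3 within the gene. Of 15 lens transcription factor genes, 11 were in both lists, among them PAX6 with 9 peaks over 6.60 kb in normoxia and 15 over 16.6 kb in hypoxia. SOX2 (525 bp) was in the hypoxia list only and MEIS1 (482 bp) in the normoxia list only. The covered ratio of this list, 2.06, was at percentile 2.78, just inside the middle 95%. The hypoxia-only share of the fiber genes was at percentile 0.97 with the 3000 bp window and at 4.78 with a window of 1000 bp.

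Several genes of the hypoxia-inducible factor (HIF) system had an H3K27ac promoter peak in the hypoxia list only. These were 5 of 8 pathway components: ARNT, the partner of HIF alpha subunits (2071 bp), the oxygen-sensing prolyl hydroxylase genes EGLN1 (745 bp) and EGLN3 (679 bp), EPAS1 (616 bp) and HIF3A (353 bp). HIF1A and VHL were in both lists. Their hypoxia-only share was at percentile 95.4, inside the middle 95%. It was at 95.6 with a window of 1000 bp, at 85.5 over all annotated peaks and at 99.8 with inferred transcript starts, an alternative added after the data were seen, where their share in both lists was at 1.44. Their covered ratio of 2.03 was lower than the random median of 3.31 (percentile 6.98). Of 41 classical HIF targets, 17 were in both lists, 13 in the hypoxia list only and 3 in the normoxia list only, and the hypoxia-only share was at percentile 46.4. The heme oxygenase gene HMOX1 (1361 bp), the repressor gene BHLHE40 (1307 bp) and the angiogenic factor gene VEGFA (1053 bp) had the widest hypoxia-only promoter peaks of the list. The normoxia-only members were STC2, PLOD1 and PDK1, a kinase that inhibits pyruvate dehydrogenase, with a peak of 289 bp. Over all annotated peaks, VEGFA had 5 peaks over 1.77 kb in normoxia and 14 over 11.8 kb in hypoxia, and PDK1 had 1 over 0.289 kb and 7 over 4.35 kb. EGLN3 had 3 peaks over 2.56 kb in normoxia and 9 over 10.3 kb in hypoxia. BNIP3L, a mitochondrial receptor that marks organelles for removal as fiber cells mature, was in both lists, with 4 peaks over 1.60 kb and 7 peaks over 10.2 kb. CDKN1B, the cell cycle inhibitor p27, had 6 peaks over 3.14 kb in normoxia and 12 over 13.9 kb in hypoxia. At LDHA, lactate dehydrogenase A, 2 peaks covered 0.545 kb in normoxia and 2 covered 1.01 kb in hypoxia. The covered ratio of the HIF targets as a list, 3.61, was at percentile 81.5 of matched random lists.

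**Figure D2:**
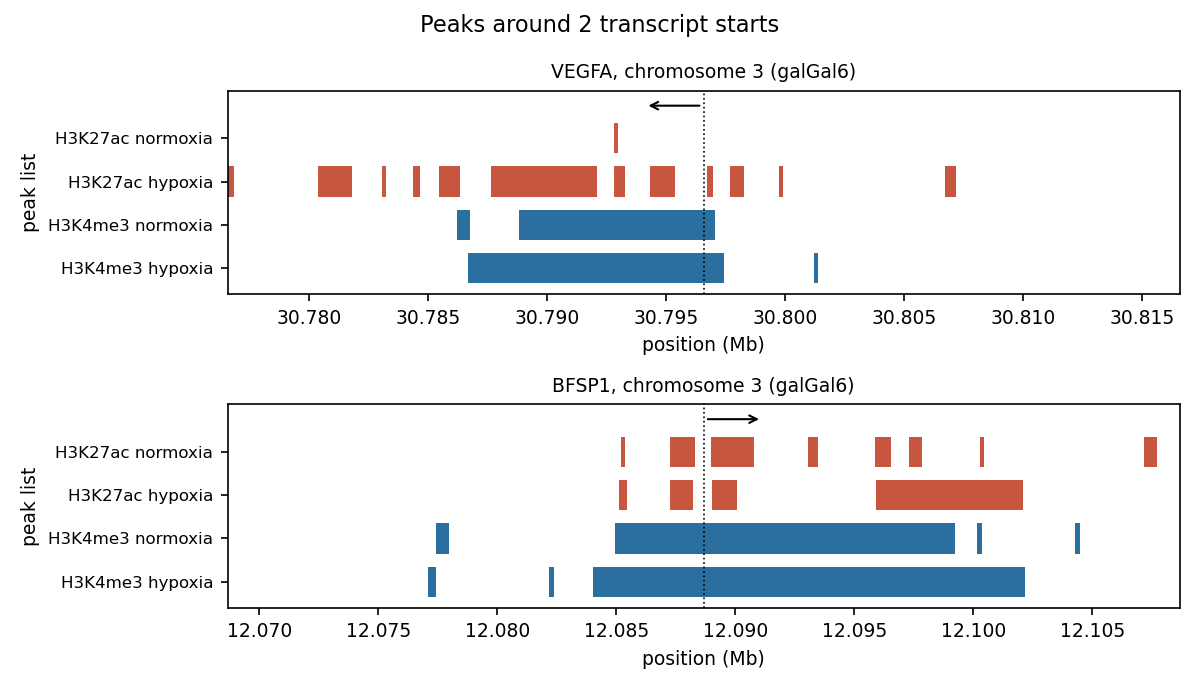
Peaks of the 4 lists (y axis) within 20 kb of the transcript starts of VEGFA and BFSP1 on chromosome 3, by position in Mb of galGal6 (x axis), with boxes to scale, dotted lines at the start inferred from the listed distances and arrows in the direction of transcription. VEGFA has 1 H3K27ac peak in normoxia and 12 in hypoxia in this window, and BFSP1 has 8 and 4.

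Genes of energy metabolism and organelle removal did not stand apart from matched random lists in their hypoxia-only shares. Mitochondrial respiration had 17 of 27 genes in both lists (percentile 99.4) and 7 in hypoxia only, such as SDHC of complex II (1082 bp) and COX4I1 of complex IV (1070 bp). COX5A was in the normoxia list only and 2 genes in neither. Glycolysis had 11 of 21 genes in both lists, 4 in neither and 6 in hypoxia only, with PFKP (2082 bp), TPI1 (2017 bp) and PFKL (1073 bp) widest. Autophagy and mitophagy had 16 of 29 in both, 5 in neither and 8 in hypoxia only, with the autophagosome protein gene MAP1LC3A (1399 bp), the mitophagy receptor gene FUNDC1 (1169 bp) and GABARAPL1 (876 bp) widest. The hypoxia-only shares of these lists were at percentiles 15.3, 23.5 and 25.2, inside the middle 95%.

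Immediate early genes, which respond to stimuli within minutes, stood apart in another way: 3 of 22 had H3K27ac promoter peaks in both lists (percentile 0.02). Another 7 had one in neither list, and 12 with a window of 1000 bp, so the low share in both lists includes promoters without H3K27ac peaks. In this list 10 genes were in the hypoxia list only, led by MYC (2023 bp), DUSP4 (1025 bp) and FOSL2 (980 bp), and 2 in the normoxia list only, JUND and BTG2. At MYC 10 peaks were annotated in normoxia and 28 in hypoxia. Of 13 oxygen-dependent chromatin demethylases, 6 were in both lists and 6 in hypoxia only, including JMJD1C (1327 bp), TET2 (1039 bp) and KDM4A (763 bp). Of 23 enzymes of histone acetylation and H3K4 methylation, 12 were in both and 9 in hypoxia only, including the methyltransferase gene KMT2A (1216 bp) and the demethylase gene KDM1A (1120 bp), while the acetyltransferase gene KAT2A (1286 bp) was in normoxia only. Heat shock and unfolded protein genes had 12 of 23 in both, 5 in hypoxia only, such as HSPD1 (2329 bp) and CALR (1162 bp), and 3 in normoxia only: HSPA8 (1204 bp), DNAJB9 and ATF6. Cell cycle and FOXO genes had 7 of 25 in both and 6 in hypoxia only, with FOXO3 (1137 bp), TOP2A (877 bp) and CDK2 (587 bp) widest. Housekeeping genes had 12 of 24 in both and 8 in hypoxia only, with RPL5 (1562 bp), PSMB2 (1449 bp) and RPL13 (1143 bp) widest. The hypoxia-only shares of these 6 lists lay inside the middle 95% with the 3000 bp window, as did those of the marker lists of other cells. Over all annotated peaks, the blood and endothelial markers were at percentile 1.05, and with inferred transcript starts the heat shock genes were at 2.28. The normoxia-only shares of the immediate early and heat shock genes were at 97.8 and 97.6 with a window of 1000 bp, and that of the HIF targets at 98.5 over all annotated peaks, all 3 inside the middle 95% with the 3000 bp window.

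Markers of other cell types were counted in the same promoter window. Of the genes listed beforehand as lens epithelial markers, 6 of 12 were in both lists and 4 in hypoxia only. These included the matrix protein gene SPARC (2897 bp), the gap junction gene GJA1 (2508 bp) and the Notch ligand gene JAG1 (1274 bp). Whether each of these genes is restricted to the epithelium was not tested. Of 24 retinal and neuronal markers, 6 had any promoter peak of either mark, with NEFL, POU4F3 and RAX in the H3K27ac hypoxia list only. Of 19 blood and endothelial markers, 6 had one, with CSF1R (209 bp) in the H3K27ac hypoxia list only and TIE1 in the H3K27ac normoxia list only. Of 15 corneal and periocular mesenchyme markers, 6 had one, with DCN (310 bp) and COL1A1 (182 bp) in the H3K27ac hypoxia list only. Of 10 pigment epithelium markers, MITF alone had one, with an H3K27ac peak of 544 bp in hypoxia only, too few genes to compare. LMO2 of the blood and endothelial markers and ELAVL4 of the retinal ones were in both lists for both marks. Over all annotated peaks, 15 retinal, 10 blood and endothelial, 10 mesenchyme and 8 pigment epithelium markers had a peak of either mark, so the presence of other cells in the samples stays open.

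**Figure D3:**
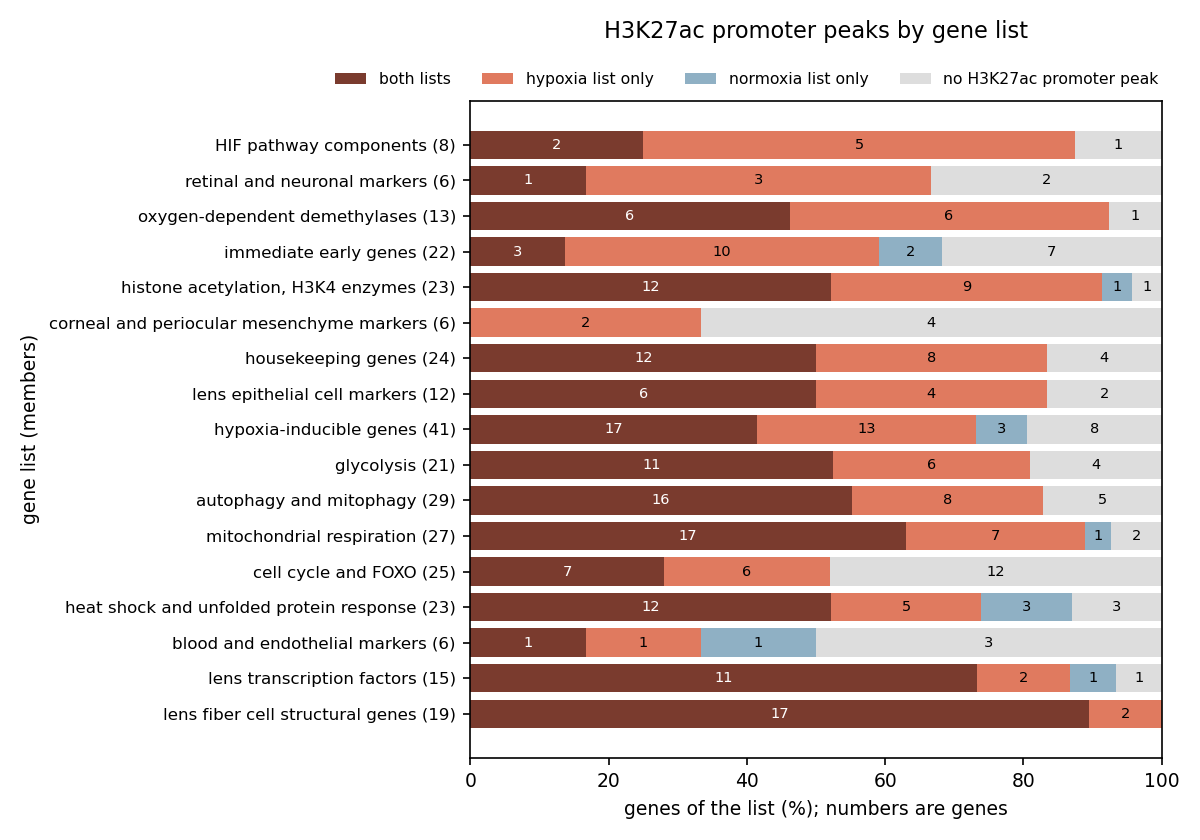
Share of genes (x axis, percent) of each list of at least 5 members (y axis, members in parentheses) by where their H3K27ac promoter peak was listed, with gene numbers in the bars. Lens fiber structural genes have 17 of 19 members in both lists, while immediate early genes have 3 of 22.

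The H3K4me3 lists of the conditions were closer to each other in size. The hypoxia list held 24987 peaks over 42.4 Mb and the normoxia list 22288 peaks over 38.6 Mb, 1.12 times the number and 1.098 times the covered length. Of the normoxia peaks, 66.5% (65.9 to 67.2%) overlapped a hypoxia peak, against 8.92% by shifts, and of the hypoxia peaks 58.8% (58.2 to 59.4%) overlapped a normoxia peak, against 8.04%. That left 10287 peaks in the hypoxia list only and 7457 in the normoxia list only. Both kinds were narrow, with medians of 368 and 405 bp against 1854 and 1717 bp for shared peaks, and few lay within 1 kb of a TSS (7.07% and 5.98%, against 59.0% and 58.7%). Every peak in the widest of 10 width classes was shared, in both lists. Among peaks at least 500 bp wide, 3774 were in the hypoxia list only and 2980 in the normoxia list only.

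**Figure D4:**
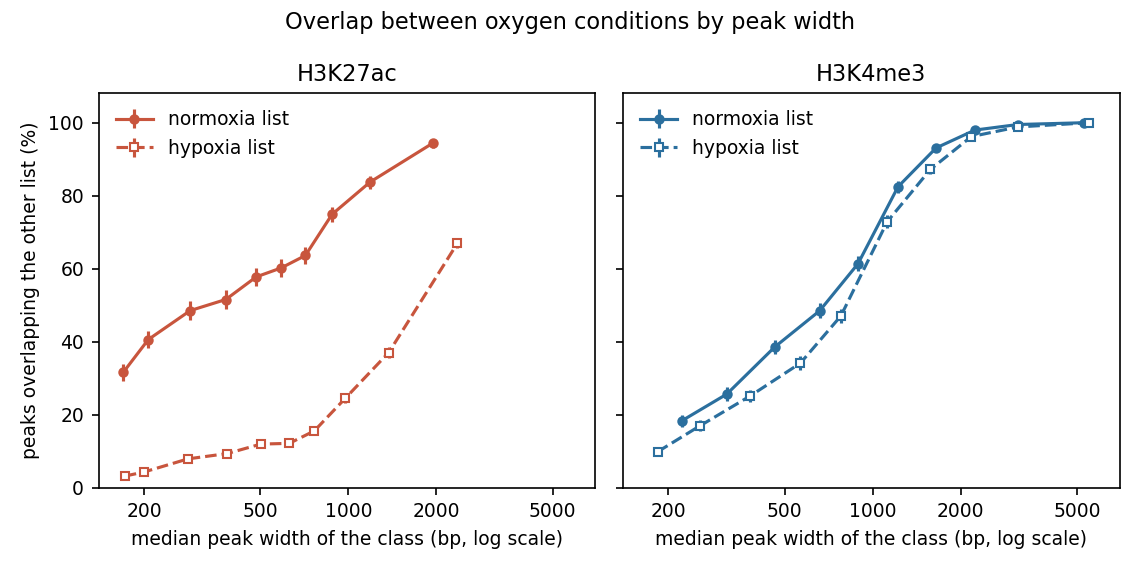
Share of peaks overlapping the other condition's list (y axis, percent, with 95% Wilson intervals over peaks) for 10 equal classes of each list ordered by width (x axis, median width in bp, log scale). Overlap reaches 100% in the widest H3K4me3 peaks of both lists, and 94.5% (normoxia list) and 67.0% (hypoxia list) in the widest H3K27ac peaks.

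At promoters, H3K4me3 was in both lists at 9909 of 10846 genes (91.4%), in hypoxia only at 559 (5.15%) and in normoxia only at 378 (3.49%). Where both lists had promoter peaks, they covered a median of 2323.5 bp in normoxia and 2530.5 bp in hypoxia, a median log2 ratio of 0.12 over 9754 genes. The widest promoter peaks of the hypoxia list only lay at the zinc finger gene ZNF532 (3640 bp on chromosome Z, 852622 to 856261), FGF19, a secreted growth factor (2969 bp), the histone methyltransferase gene ASH1L (2575 bp), CLIP1, a microtubule plus-end protein (2482 bp), the Wnt receptor gene RYK (2421 bp), ASTL (2375 bp), CDK18 (2357 bp), FKBP9 (2191 bp), the chromatin reader gene ZMYND8 (2153 bp) and ZFX (1914 bp). Those of the normoxia list only lay at SH3BGRL2 (3283 bp), the actin nucleator gene LMOD2 (2203 bp), FOXO1, a forkhead transcription factor (1766 bp on chromosome 1, 171900834 to 171902599), PPIL6 (1755 bp), USP54 (1731 bp), the synaptotagmin gene SYT10 (1690 bp), LAMP5 (1601 bp), FAM241A (1512 bp), the growth factor gene BMP6 (1450 bp) and the potassium channel gene KCNK12 (1449 bp). No H3K4me3 peak of the hypoxia list was annotated to FOXO1, LMOD2, BMP6, PPIL6, SYT10 or KCNK12, and none of the normoxia list to FGF19 or ASTL. The other named genes had peaks of the other list too, outside the promoter window. At the hypoxia-only ones these covered from 0.262 kb (ZNF532) to 9.27 kb (CLIP1) in normoxia. SH3BGRL2 had 14.2 kb in normoxia and 13.4 kb in hypoxia over all annotated peaks.

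The genes reported in any case showed H3K4me3 at the TSS in both conditions, apart from CRYAA. The promoter peak of BNIP3L was 6120 bp in normoxia and 7413 bp in hypoxia, that of VEGFA 8232 and 10764 bp, of EGLN3 5029 and 4697 bp, of PDK1 2515 and 1948 bp, of LDHA 4302 and 3441 bp and of CDKN1B 9292 and 7633 bp. Those of the other 3 were 9445 and 18518 bp at MIP, 14308 and 18179 bp at BFSP1, and 19507 and 20562 bp at the eye transcription factor gene PAX6. CRYAA had no H3K4me3 peak within 3000 bp of its TSS, with 4.18 kb in normoxia and 9.16 kb in hypoxia listed farther off. Of the fiber structural genes, 17 of 19 were in both lists, and CRYBB3, a beta crystallin, was in hypoxia only (1787 bp). Their covered ratio of 1.42 was at percentile 98.8, against a random median of 1.15. Without ASL1 it was 1.26, at percentile 83.1, and without MIP 1.39, at 97.4, so the excess rested largely on ASL1.

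Most genes of the other lists had H3K4me3 promoter peaks in both conditions. These were 8 of 8 HIF components, 40 of 41 HIF targets (percentile 99.5), 19 of 21 glycolysis genes, 27 of 27 mitochondrial genes (99.2), 29 of 29 autophagy genes (99.5), 15 of 15 lens transcription factors, 12 of 12 lens epithelial markers, 13 of 13 oxygen-dependent demethylases, 22 of 23 histone enzymes, 24 of 25 cell cycle genes (97.8), 21 of 22 immediate early genes (98.0), 22 of 23 heat shock genes and 23 of 24 housekeeping genes. All of these lists lay above the random median, with glycolysis lowest at percentile 72.2 and housekeeping genes at 82.4. A high share in both lists was thus not particular to any of them. Members, like the genes of the random lists, have a promoter peak of either mark, so listed names without one are left out of these shares. The 51 HIF target names gave 41 members and the 32 mitochondrial names gave 27. With a window of 1000 bp, the HIF targets were at percentile 87.9, the mitochondrial genes at 97.2, the cell cycle genes at 81.0 and the immediate early genes at 92.6. With inferred transcript starts the mitochondrial genes were at 95.8, the autophagy genes at 94.1, the cell cycle genes at 88.4 and the immediate early genes at 92.6, all inside the middle 95%. Of the remaining members, KLF2 (343 bp) and the small heat shock protein gene HSPB1 (1030 bp) were in hypoxia only and FOXO1 in normoxia only. HMOX1, the glycolysis genes PFKM and GYS1, KMT2C and 1 of the 2 gene IDs named RPL3 had no H3K4me3 promoter peak in either list. Among markers of other cells, the mesenchyme genes COL1A2 (686 bp), TBX18 (558 bp) and COL5A1 (196 bp) were in normoxia only, 3 of 6 members (percentile 99.6), and 2 of 6 were in both lists (1.79). With inferred transcript starts 3 of 5 members were in normoxia only and 1 in both, at percentiles 99.9 and 0.555. Over all annotated peaks 2 of 10 members were in normoxia only and 5 in both, at percentiles 86.7 and 21.3. Of the 6 blood and endothelial members, 2 were in both lists (percentile 0.42), HBZ (1462 bp) and TIE1 (204 bp) in hypoxia only and RUNX1 (668 bp) in normoxia only. The share in both lists was at 0.795 with a window of 1000 bp, 1.13 with inferred transcript starts and 10.6 over all annotated peaks. The normoxia-only share of these blood and endothelial genes was at 83.3, and at 98.4 over all annotated peaks. The retinal gene VSX1 (169 bp) was in hypoxia only with 3 of 6 retinal members in both, and MITF was in both. Over all annotated peaks the shares in both lists were at percentile 0.62 for the retinal and 0.21 for the pigment epithelium markers, and at 98.7 for the histone enzymes. Over both marks, 136 percentiles were computed for 17 lists, and 14 lay outside the middle 95%. The shares of a list depend on each other and some lists share genes, so no number expected by chance is given.

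Few promoters were in the hypoxia list only for both marks. Of the 4370 genes with H3K27ac in the hypoxia list only, 3387 (77.5%) had H3K4me3 in both lists, 700 had no H3K4me3 promoter peak and 186 had H3K4me3 in hypoxia only as well. Among the 8383 genes with promoter peaks of both marks, those 186 compare with 124 expected from independent lists, a ratio of 1.501 (1.37 to 1.63, exact binomial interval of the shared count) and an odds ratio of 2.54. H3K27ac was in the hypoxia list only at 3670 of the 8383 genes. It was so at 186 of the 283 genes with H3K4me3 in hypoxia only, and also at 97 of the 140 with H3K4me3 in normoxia only. The excess was thus not particular to the same direction in both marks. Promoters in the normoxia list only for both marks numbered 15, against 8.03 expected. Across genes, the log2 ratio of promoter coverage of H3K27ac, with 500 bp added to each value, was only weakly related to that of H3K4me3 (Spearman's rho 0.085 over 8383 genes, which are not independent replicates). Between overlapping peaks of the marks in the hypoxia lists, the ratio of observed to expected hypoxia-only pairs was 1.04.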

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

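The gap rule, the 500 bp minimum width, lists of equal length, autosomes only, inferred transcript starts and leaving out each member of a gene list were chosen after the data were seen. Shares overlapped are given as normoxia then hypoxia peaks. For H3K27ac they were 50.2% and 15.9% with 50% of either peak, 15.6% and 5.29% with 50% of both, 76.9% and 27.1% with gaps up to 1000 bp, 74.5% and 29.5% for peaks at least 500 bp wide, and 44.9% and 39.8% with the hypoxia list reduced to as many of its widest peaks as the normoxia list holds. For H3K4me3 they were 62.8% and 55.4%, 46.8% and 41.8%, 72.7% and 65.7%, 81.7% and 77.9%, and 65.5% and 64.7% under the same rules. Normoxia-only peaks numbered 13093 (H3K27ac) and 11856 (H3K4me3) with 50% of both, 3585 for H3K27ac with gaps allowed, and 2105 and 2980 among peaks at least 500 bp wide. Hypoxia-only peaks numbered 17823 and 3774 among peaks at least 500 bp wide, and 9332 for H3K27ac with lists of equal length. By construction, a stricter rule lowers shares and raises counts of unshared peaks, and a gap does the reverse. The minimum width lowered all 4 counts, and lists of equal length lowered the hypoxia-only counts and raised the normoxia-only counts, to 8549 (H3K27ac) and 7681 (H3K4me3). Autosomes alone moved no overlap share past its interval and no count by 1.5 times.

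Hypoxia-only H3K27ac promoters were 41.0% of genes with all annotated peaks and 42.0% with inferred starts. Normoxia-only H3K27ac promoters were 8.23% with a 1000 bp window, 3.03% with all peaks and 4.61% with inferred starts (350 genes against 561). For H3K4me3 the hypoxia-only share was 4.21%, 6.42% and 4.68% under these settings and the normoxia-only share 2.65%, 4.89% (617 genes against 378) and 2.90% (241 genes). The ratio of observed to expected hypoxia-only promoters of both marks was 1.29 with a 1000 bp window, 1.69 with all peaks and 1.04 between overlapping peaks. The cause of these shifts was not tested. Of the percentiles of the both, hypoxia-only and normoxia-only shares of gene lists under alternatives, 272 stayed on their side of the bounds, 12 moved inside the middle 95% and 10 moved outside it. None of those outside the middle 95% crossed the median. Covered ratios were not computed under these settings. For the 2 ratios outside the middle 95%, both of the fiber structural genes, each member was left out in turn: 36 percentiles stayed outside, and those of H3K4me3 without ASL1 (83.1) and without MIP (97.4) moved inside.

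No paired analysis was possible because the lists carry no replicates. For the same reason the planned comparisons of scaling (trimmed means, size factors, totals), count models, low-count filters, pseudocounts, fold thresholds, a stricter caller threshold, peaks of the whole table, estimated correlation, highest-mean peak and leaving out each replicate were not run. Unknown depth limits every count of peaks: a place in the hypoxia list only may lie just under the caller's threshold in normoxia. The share of hypoxia H3K27ac peaks with a normoxia peak was 19.3% without and 27.1% with gaps up to 1000 bp. The share of normoxia H3K27ac peaks with a hypoxia peak was 60.7% and 76.9%. Circular shifts were not run for the gap rule, so its rise by chance nearness is unknown.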

Other observations

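The test of covered length, the ranking of genes by covered length and the counts per chromosome were chosen after the results they describe were seen. Summed over all peaks annotated to a gene, the largest added H3K27ac coverage lay at ARID1B. This gene, which encodes a subunit of BAF chromatin remodelers, had 16.7 kb over 21 peaks in normoxia and 52.2 kb over 44 peaks in hypoxia. FGFRL1, a receptor of the fibroblast growth factor family, had 33.5 and 68.6 kb, the crystallin-activating transcription factor gene MAF 32.2 and 65.8 kb, and the cytoskeletal spectrin gene SPTBN1 10.3 and 43.3 kb. CDH2, the N-cadherin of lens fiber membranes, had 16.2 and 43.1 kb, KLF9 21.8 and 49.3 kb, the splicing regulator gene QKI 5.07 and 32.1 kb, and BIN1 10.2 and 36.4 kb. This ranking is by added length, and the whole hypoxia list covered 3.34 times the normoxia list. Ratios were lower than that at ARID1B (3.13), CDH2 (2.66), KLF9 (2.26), FGFRL1 (2.05) and MAF (2.04). They were higher at QKI (6.32), SPTBN1 (4.20) and BIN1 (3.57). Some genes, among them fiber and eye genes, had less coverage in hypoxia. The beta crystallin gene CRYBB2 had 4.85 kb in normoxia and 1.88 kb in hypoxia, the eye field gene SIX3 11.6 and 8.64 kb, the retinoic acid receptor gene RARA 6.92 and 3.59 kb, and FAIM2 7.04 and 1.89 kb.

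H3K4me3 coverage differed widely between the lists at a few loci. The delta crystallin gene ASL1 had 8.31 kb in normoxia and 35.6 kb in hypoxia. A domain near MIP that also carries the annotations APOF and STAT2 spanned 18.5 kb in hypoxia. HERC4 had 15.2 and 37.3 kb, and RAB40B, next to FN3K and FN3KRP, 17.4 and 39.2 kb. STK11, the kinase LKB1, had 33.1 kb in normoxia and 12.4 kb in hypoxia, MFSD2B 34.8 and 15.8 kb, SBNO2 39.0 and 21.6 kb, and the RNA methylation reader gene YTHDF1 26.7 and 9.98 kb.

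The first pattern is the excess of H3K27ac peaks in the hypoxia list, 2.95 times the normoxia number. Splitting of broad domains into more pieces would leave covered length alike, and the ratio of covered lengths of 3.34 argues against it as the whole cause. A uniformly more sensitive hypoxia list would contain nearly all strong normoxia peaks. Of the widest 25% of normoxia peaks, 87.0% (85.9 to 88.0%) overlapped a hypoxia peak, between the bounds of 75% and 90% set for the test, so a difference in depth, library yield or pooling cannot be told apart from a response to oxygen here, with no signal per library. If the normoxia lenses were dissected at 0 h, time in culture cannot be told apart from oxygen either. A response led by hypoxia-inducible genes was not seen as an excess of those genes (percentile 46.4), but 41 genes leave a modest excess open.

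The second pattern is chromosome Z, a sex chromosome that male birds carry as a pair and females once beside W. Its H3K27ac ratio of hypoxia to normoxia peaks was 4.75 (4.29 to 5.26, counting peaks), against 3.05 to 3.29 on chromosomes 1 to 5, while its H3K4me3 ratio was 1.11. At the same hypoxia width, chromosome Z peaks were also in normoxia 0.724 times (0.654 to 0.796) as often as those of chromosomes 1 to 5. This goes against a lower signal of chromosome Z with a stricter normoxia list only if genomic classes are alike, and they were not matched. On chromosomes 1 to 5 the hypoxia to normoxia ratio was 1.92 within 1 kb of a TSS. Among intron and distal intergenic peaks it was 3.61, so a different mix of classes stays open. A candidate explanation is a smaller share of males among the normoxia H3K27ac lenses. Chromosome W had a ratio of 1.6 (0.683 to 3.94) over 26 peaks, too few to decide, and an oxygen response particular to chromosome Z was not tested.

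The third pattern is chromosome size: chromosomes 1 to 5 had a ratio of hypoxia to normoxia H3K27ac peaks of 3.17 and chromosomes 21 to 33 of 1.99, a quotient of 1.59 (1.498 to 1.69). The quotient was 1.15 (1.03 to 1.29) within 1 kb of a TSS and 1.66 (1.495 to 1.84) among intron and distal intergenic peaks, which argues against a larger share of promoter peaks on small chromosomes as the whole cause. Base composition, which differs between small and large chicken chromosomes, stays open because no genome sequence was used, and no biological explanation was tested.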
